A study of Homo sapiens with 39 samples.

How the data were processed

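RNA-seq measured polyadenylated RNA in 2 human cell lines: SUDHL4, from a diffuse large B-cell lymphoma, and LoVo, from a colorectal carcinoma. Cells received UNC7040, UNC7263 or the solvent DMSO, per the labels. The 13 libraries form 5 groups by cell line and treatment. SUDHL4 has 3 libraries each for DMSO, UNC7040 and UNC7263, and LoVo has 2 each for UNC7040 and UNC7263. Per the labels' protocols, RNA was enriched for poly-A tails, prepared with the NEBNext Ultra II kit and sequenced as paired-end reads of 150 bp on an Illumina HiSeq. The doses and times of treatment are not given in the sources used here. The labels also do not say that replicates are separate cultures, so the p-values measure the spread between these libraries, which may be technical. The series also holds 26 ChIP-seq samples in 13 groups, which were not analysed here.

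The submitters' processing notes name STAR 2.6.1c, HTSeq and DESeq2, besides Bowtie2, SAMtools, Picard, deepTools and MACS2, and the builds hg38, GRCh38 and mm10, with no statement of which tool or build served which assay. The authors deposited 3 tables of results, each for 1 comparison: UNC7040 against DMSO in SUDHL4, UNC7263 against DMSO in SUDHL4, and UNC7040 against UNC7263 in LoVo. Per the file headers, whose column names are those of DESeq2, each deposited table gives per gene a mean signal (the mean of counts divided by size factors), a log2 fold change with its spread, a p-value and an adjusted p-value. Both SUDHL4 tables hold the same mean for all 23183 genes, so the mean runs over the libraries of 1 joint fit. The tables hold 0 columns of per-sample values. Depth per library is therefore unknown here, and no replicate could be inspected, left out or reassigned. The median gene had a mean normalized count of 65.6 in SUDHL4 and 247 in LoVo, and the 10 highest genes took 5.33% of the sum of the means in SUDHL4 and 9.20% in LoVo. Annotation, filters and the kind of fold-change shrinkage are not given in the sources used here.

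The deposited log2 fold changes behave as estimates shrunken towards 0 with a heavy-tailed prior, since at low means they lie near 0 with a constant spread and their ratio to that spread is not the one behind the deposited p-value. Estimates and standard errors were first recovered by inverting a normal likelihood with a Cauchy prior. The prior's scale was set so that recovered and deposited test statistics had a median ratio of 1 in genes with a mean above 200. The unshrunken estimate used was the statistic behind the deposited p-value times the recovered standard error. Only where that p-value was 0 was the inverted estimate used. An unshrunken estimate can therefore lie slightly below the deposited change, as for INHBE with UNC7040. The scale came to 0.223 for UNC7040 and 0.0838 for UNC7263 in SUDHL4, and to 0.0589 in LoVo. Among genes with a mean of at least 10, the recovered statistic lay within 0.3 (as a difference or a share) of the deposited one in 100% of 15493 genes for UNC7040, 99.8% for UNC7263 and 99.1% of 16114 genes in LoVo. Changes are given as these unshrunken log2 estimates with 1 standard error, and calls rest on the adjusted p-value below 0.05 in the authors' deposited table. For called genes the deposited fold change was a median 0.924 times the unshrunken one for UNC7040, 0.849 times for UNC7263 and 0.878 times in LoVo. Group levels in SUDHL4 were derived from the mean and both changes, with equal weights for the 3 groups.

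The difference between UNC7040 and UNC7263 in SUDHL4 was computed from both tables with a two-sided Wald test. The plan named the deposited fold changes for this test. It used the recovered unshrunken estimates in their place, because the deposited ones are shrunken. Both compounds were set against the same DMSO libraries, so the DMSO variance was removed through the dispersion that each table's mean, change and standard error imply. Benjamini-Hochberg adjustment ran over the 15466 genes with a mean of at least 10 and recovered estimates in both tables, with a threshold of 0.05. The difference of this contrast between the cell lines was tested per gene with a two-sided z test and the same adjustment. That test ran over the 10279 genes with a mean of at least 50 in both lines. Scale and centring were checked: the median unshrunken change of genes with a mean of at least 50 was 0.003 for UNC7040, -4.2e-05 for UNC7263 and -0.006 in LoVo. The median standard error among genes with a mean above 200 was 0.0766 in each SUDHL4 contrast against DMSO and 0.108 in LoVo.

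Before the data were examined, 39 gene lists, the tests, the thresholds and the rule for named genes were fixed. Exceptions are the list tests between cell lines and the tests named in the closing section as chosen later. The use of unshrunken estimates for the difference between the compounds in SUDHL4 was also chosen later, once the deposited changes were seen to be shrunken. The lists are PRC1 subunits, PRC2 subunits, HOX genes, developmental regulators, CDK inhibitors, germinal centre B cell, plasma cell, memory B cell and activation, MHC class II, MHC class I, interferon-stimulated genes, cholesterol synthesis, fatty acid synthesis, lysosome, integrated stress response, unfolded protein response, heat shock, oxidative stress (NRF2), metallothioneins, G2/M, S phase, p53 targets, ribosome biogenesis and MYC, B-cell receptor and immediate early genes, NF-kB targets, glycolysis and hypoxia, apoptosis regulators, intestinal differentiation, Wnt targets and intestinal stem, mesenchymal and matrix, ribosomal proteins, mitochondrial genome, nuclear-encoded respiratory chain, replication-dependent histones, and markers of T cells, myeloid cells, fibroblasts, epithelial cells and B cells. They hold 782 symbols, of which 724 were measured, 2 of them under an older name. Lists with at least 5 members carrying a test statistic were tested two-sided with cameraPR of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. An estimated correlation needs per-sample values and was impossible, so presets of 0.05 and 0.1 were run instead, besides ranks, log2 changes as the statistic and another background.

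The named genes are, per comparison and among called genes with a mean of at least 50, the 10 largest rises, the 10 largest falls, the 5 smallest p-values per direction, up to 4 called members per list, and always CBX8, RNF2, EZH2, PRDM1, BCL6, CDKN1A, CDKN2A and MYC. Positions come from the reference table of GRCh38.p14, which held 17641 of the SUDHL4 symbols and 16450 of the LoVo symbols. Changes of both compounds were correlated across genes with a mean of at least 50 and set beside 100 simulated draws of unchanged groups that share the DMSO libraries. Overlaps between cell lines used a one-sided hypergeometric test. Shares of higher calls by expression quartile used Fisher's exact test. The alternatives were other filters, thresholds of 0.01 and 0.1, a size limit of 1 on the log2 scale, re-centring, quartiles of the derived control-group mean in place of the mean, other variances for the compound difference and the shrunken estimates.

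The recovery and the Wald test were tested on simulated data with 200 changed genes. The simulation shrank changes with the same model that the recovery inverts, so it cannot test that model. It also took the dispersions as known, which those of 2 or 3 libraries are not. The counts may therefore overstate power and understate false calls. For UNC7040 against UNC7263 in SUDHL4, 21, 34, 36 and 44 of 50 genes were called at 1.25-fold, 1.5-fold, 2-fold and 4-fold, with 9 of 15345 unchanged genes called, among 15543 genes. For LoVo, 9, 28, 40 and 42 of 50 were called at the same folds, with 5 of 15845 unchanged genes called, among 16042 genes. Changed genes that fell outside the filters count as not called. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3. The mitochondrial genome list had 0 measured members and was not used here.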

Results

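Transcript levels were compared between cells given UNC7040, cells given UNC7263 and cells given DMSO. CBX8, named in the title of the series, is a chromodomain subunit of Polycomb repressive complex 1 (PRC1), which keeps developmental genes silent. The title also names a positive allosteric modulator, and the labels do not say which compound that is. SUDHL4 lymphoma cells had 3 libraries per group and LoVo colorectal cells had 2. Changes are unshrunken log2 estimates ± 1 standard error, and a gene rose or fell only if its adjusted p passed. How many libraries show each direction, and the depth of each library, are unknown, since the tables hold group results.

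The first question was which genes UNC7040 changes in SUDHL4. Genes of the integrated stress response, the ATF4 program that cells start when translation initiation is held back, were higher with UNC7040 than with DMSO. ATF5, a transcription factor of this program, rose by 2.82 ± 0.07 on the log2 scale, from a derived mean of 1109 normalized counts with DMSO to 7851 with UNC7040. CHAC1, a glutathione-degrading enzyme, rose by 4.83 ± 0.41, and PSAT1, an enzyme of serine synthesis, rose by 1.71 ± 0.06. Of the 30 listed members with an adjusted p, 28 rose and 0 fell, also when adjusted over the list alone, with a median change of 1.07 (cameraPR, adjusted p = 3.0e-195). The other 2 members, named after their values were seen, were DDIT3 at 0.49 ± 0.25 and PPP1R15A at 0.06 ± 0.09. ATF4 itself, also chosen after its value was seen, rose by 0.63 ± 0.05.

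Outside that list, the largest rises of UNC7040 were those of INHBE, an inhibin subunit (6.53 ± 0.57), and ULBP1, a ligand of the NK-cell receptor NKG2D (3.94 ± 0.43). The derived mean of INHBE with DMSO was only about 3.05 normalized counts, so the size of its rise is uncertain. ASS1, which makes argininosuccinate in arginine synthesis, rose by 3.58 ± 0.12, and SLC6A9, a glycine transporter, by 2.74 ± 0.14. SPX (3.42 ± 0.21) and MFAP4 (3.32 ± 0.29) were also among the 10 largest rises, with ATF3 (2.36 ± 0.30) and STC2 (2.14 ± 0.10) from the stress list. The largest falls were those of AGR2, a disulfide isomerase of secretory cells, which fell by 2.40 ± 0.40, CDH19, a cadherin (-2.37 ± 0.36), and TNNI1, a troponin of slow muscle (-2.22 ± 0.17). VNN1 (-1.99 ± 0.25), RASSF6 (-1.73 ± 0.12), LAMP3 (-1.66 ± 0.32), MRAS (-1.59 ± 0.14), MYRFL (-1.56 ± 0.29) and MYBPH (-1.42 ± 0.09) also fell. In GRCh38.p14, INHBE lies on chromosome 12 from 57455307 to 57458025, CHAC1 on chromosome 15 from 40953471 to 40956512, and ATF5 on chromosome 19 from 49928906 to 49933935.

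**Figure D1:**
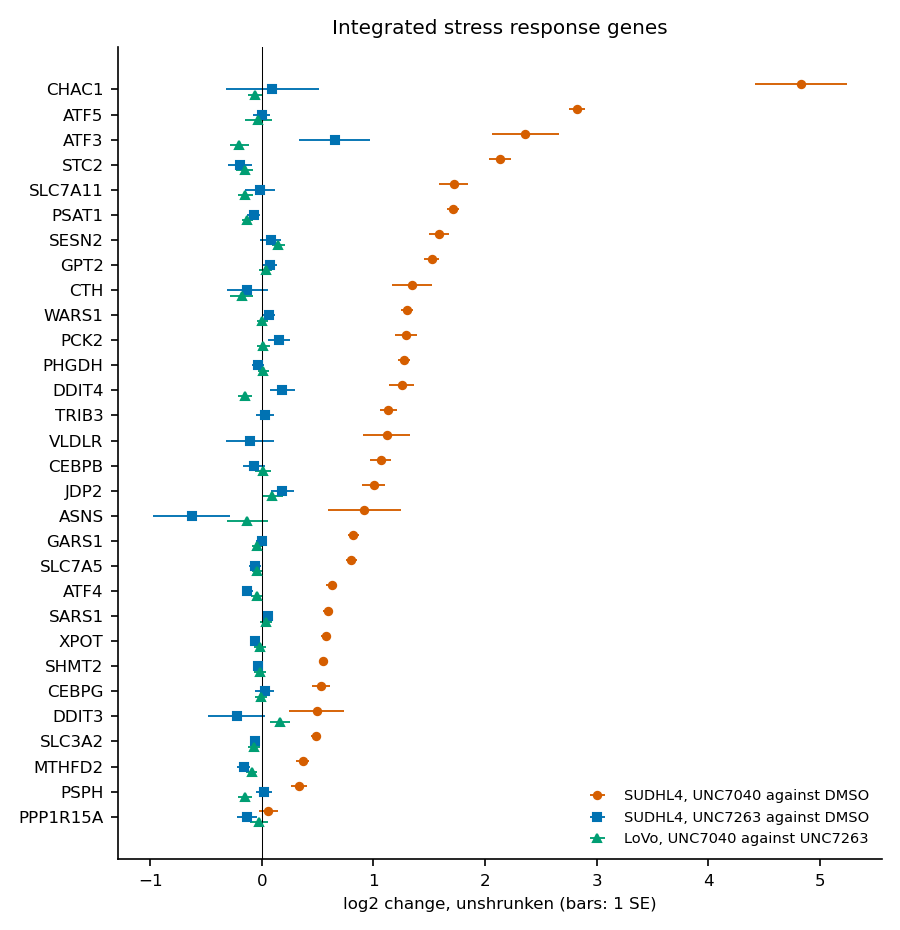
Integrated stress response genes with a mean of at least 50 normalized counts in SUDHL4; points are unshrunken log2 changes and bars 1 standard error, from groups of 3 libraries (SUDHL4) or 2 (LoVo). The UNC7040 changes in SUDHL4 have a median of 1.07, against -0.03 for UNC7263 in SUDHL4 and -0.03 for UNC7040 against UNC7263 in LoVo; a few members have no recovered LoVo estimate.

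Interferon-stimulated genes, the antiviral effectors, were lower with UNC7040, with a median change of -0.55 over 40 members. Of these, 22 fell and 0 rose, and 27 fell when adjusted over the list alone (adjusted p = 3.0e-12). IFIT1, which binds viral RNA, fell by 2.03 ± 0.36, OASL by 0.96 ± 0.16 and SAMD9L by 0.81 ± 0.13. The median dispersion of this list was 4.88 times that of lists matched on mean count. Nuclear-encoded subunits of the respiratory chain were lower too: 15 of 20 fell and 0 rose, with a median of -0.26 (adjusted p = 5.2e-13). Cytochrome c (CYCS, -0.59 ± 0.07), NDUFA4 (-0.50 ± 0.08) and the ATP synthase subunit ATP5MC1 (-0.47 ± 0.06) were among them. The 2 genes with the smallest p among the falls were MTCO3P12 (-0.99 ± 0.05) and DCN, and MTATP6P1 (-0.80 ± 0.05) followed; MTCO3P12 and MTATP6P1 are nuclear copies of mitochondrial genes with near-identical sequence, so reads may be misassigned and their values are uncertain.

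Lists of growth and division genes were lower by smaller amounts with UNC7040. In the ribosome biogenesis and MYC list 14 of 24 members fell, 15 when adjusted over the list alone, with a median of -0.17 (adjusted p = 6.6e-11), among them the nucleolar proteins GNL3 (-0.48 ± 0.06) and NOP58 (-0.38 ± 0.05). MYC itself stood at 0.01 ± 0.04 and did not pass. Of 23 G2/M genes 14 fell, 15 when adjusted over the list alone, with a median of -0.17 (adjusted p = 6.1e-09), such as HMMR (-0.43 ± 0.07) and the kinetochore motor CENPE (-0.38 ± 0.07). Of 24 S-phase genes 13 fell and 1 rose, or 16 and 1 when adjusted over the list alone, with a median of -0.15 (adjusted p = 4.3e-06), for example RRM2, a subunit of ribonucleotide reductase (-0.26 ± 0.03). Heat-shock genes had 8 of 14 members lower and 1 higher, the same when adjusted over the list alone, with a median of -0.17 (adjusted p = 3.2e-06), led by the chaperone HSPA8 (-0.50 ± 0.05).

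Several groups were higher with UNC7040. Of 14 NF-kB targets 8 rose and 1 fell, or 9 and 1 when adjusted over the list alone, with a median of 0.19 (adjusted p = 4.3e-05): the subunits NFKB2 (0.68 ± 0.05) and RELB (0.55 ± 0.11) and the cytokine LTA (0.58 ± 0.10) rose, and BCL2A1 fell by 0.51 ± 0.14. Of 14 NRF2 targets 7 rose, with a median of 0.18 (adjusted p = 2.6e-06), including heme oxygenase HMOX1 (0.67 ± 0.09), PGD (0.42 ± 0.05) and SLC7A11 (1.72 ± 0.13), which the stress list also holds; adjusted over the list alone 7 rose and 1 fell. Of 12 MHC class I genes 5 rose and 2 fell, also when adjusted over the list alone, with a median of 0.07 (adjusted p = 0.0021), and members whose reads are alike are uncertain. Lysosomal genes had 9 of 27 higher and 2 lower, 10 and 2 when adjusted over the list alone, with a median of 0.16, among them ATP6V0A1 (0.48 ± 0.06); their adjusted p of 0.00051 became an adjusted p of 0.0798 at a correlation of 0.1. Ribosomal proteins had 13 of 35 higher and 0 lower, also when adjusted over the list alone, but a median of only 0.02, with RPL13A at 0.32 ± 0.05. Their adjusted p of 0.00095 became an adjusted p of 0.112 at a correlation of 0.1.

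Of 26 PRC1 subunits 9 rose and 1 fell with UNC7040, the same when adjusted over the list alone, with a median of 0.13. BMI1 (0.64 ± 0.07) and PHC1 (0.39 ± 0.08), subunits of canonical PRC1, and the co-repressor BCOR (0.23 ± 0.05) rose, and PCGF5 fell by 0.26 ± 0.06. The list's adjusted p of 0.0021 became an adjusted p of 0.112 at a correlation of 0.1. CBX8 stood at -0.03 ± 0.09 and RNF2 at 0.08 ± 0.08, and neither passed. Of 13 PRC2 subunits 2 rose and 3 fell, 2 and 4 when adjusted over the list alone (adjusted p = 0.689), with EZH2, the methyltransferase, at -0.20 ± 0.04. Among HOX genes, classical Polycomb targets, 1 of 10 rose, HOXA3 (0.90 ± 0.35), and 0 when adjusted over the list alone (adjusted p = 0.443). Among developmental regulators 1 of 5 rose, PAX2 (0.82 ± 0.32), and 0 when adjusted over the list alone (adjusted p = 0.751). Only 20 of 39 listed HOX genes and 17 of 60 listed developmental regulators were measured, so these counts leave most listed genes untested. Of members with a mean of at least 10, 9 of 13 HOX genes lay above 0 (median 0.09), as did 6 of 9 developmental regulators (median 0.26).

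B-cell groups moved both ways with UNC7040, and none of their lists was called. Germinal centre genes had 5 of 23 higher and 5 lower, 7 and 5 when adjusted over the list alone: BCL7A (0.64 ± 0.05) and S1PR2 (0.58 ± 0.08) rose, and STAP1 (-0.57 ± 0.07) and MME (-0.52 ± 0.07) fell. Plasma cell genes had 3 of 15 higher and 5 lower, 4 and 5 when adjusted over the list alone, with JCHAIN at -0.77 ± 0.06, MZB1 at -0.68 ± 0.06 and XBP1 at 0.34 ± 0.06; their median was 0.03 while their test pointed down. Memory and activation genes had 3 of 13 higher and 4 lower, 3 and 5 when adjusted over the list alone, with CXCR3, a chemokine receptor, at -1.21 ± 0.14 and TNFRSF13C at 0.74 ± 0.07. MHC class II genes had 3 of 14 higher and 2 lower, also when adjusted over the list alone. B-cell markers had 2 of 8 higher and 2 lower, 2 and 3 when adjusted over the list alone, with CD22 at 0.74 ± 0.05 and PTPRC at -0.37 ± 0.04; their median was -0.07 while their test pointed up. PRDM1 (0.35 ± 0.23) and BCL6 (0.05 ± 0.06), regulators that oppose each other in the germinal centre, did not pass.

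Of the remaining lists, cholesterol synthesis was called higher with UNC7040, with 6 of 24 higher and 0 lower, or 4 when adjusted over the list alone, a median of 0.09 and an adjusted p of 0.0026, which became an adjusted p of 0.112 at a correlation of 0.1. Fatty acid synthesis had 3 of 10 higher and 1 lower, CDK inhibitors 2 of 7 higher and 1 lower, and the unfolded protein response 4 of 16 higher and 2 lower. CDKN1A rose by 0.56 ± 0.20, and CDKN2A, at 0.03 ± 0.07, did not pass. The p53 targets had 6 of 21 higher and 3 lower, apoptosis regulators 4 of 11 and 2, glycolysis and hypoxia 4 of 18 and 2, with VEGFA at 0.99 ± 0.10 and LDHA at -0.36 ± 0.04. B-cell receptor and immediate early genes had 3 of 18 higher and 2 lower, with ETV5 rising by 0.98 ± 0.14; their median of -0.01 was of opposite sign to their test. Histones had 1 of 11 higher, Wnt targets 1 of 3 (LEF1, 0.38 ± 0.09), and mesenchymal genes 0 of 5 by the authors' test and 0 at an unadjusted p under 0.05. None of these lists except cholesterol synthesis was called. Metallothioneins, with 2 of 4 members lower (MT2A, -0.58 ± 0.11), were too few for a list test.

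Among markers of T cells, myeloid cells, fibroblasts and epithelial cells, only DCN and TRAC passed with UNC7040. The fibroblast list was called lower (adjusted p = 2.0e-05) through DCN, a matrix proteoglycan, which fell by 1.27 ± 0.07; only 3 members had an adjusted p, and by ranks its adjusted p was 0.112. TRAC, a T-cell receptor segment, rose by 0.65 ± 0.14, the 1 of 5 T-cell markers that passed. Epithelial markers had 1 member with an adjusted p and myeloid markers 2, and 0 of either passed or reached an unadjusted p under 0.05. In all, 3495 of 13295 genes changed with UNC7040, 1578 upward and 1917 downward, of which 62 and 51 exceeded 1 in the deposited log2 fold change. Of 36 lists tested 8 were higher and 7 lower, and 11 of these 15 were called at a correlation of 0.1. With log2 changes as the statistic, S phase, lysosome, ribosomal proteins, MHC class I, PRC1 and cholesterol synthesis were not called, and by ranks ribosomal proteins, MHC class I and fibroblast markers were not.

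The second question was which genes UNC7263 changes in SUDHL4. Genes of the B-cell receptor and immediate early list, called immediate early genes for short below, were lower with UNC7263 than with DMSO. Growth-factor and antigen-receptor signals switch on such genes, the immediate early ones within minutes. FOS fell by 0.84 ± 0.11, FOSB by 0.95 ± 0.13 and the phosphatase gene DUSP6 by 0.74 ± 0.15. Of 14 listed members 7 fell and 0 rose, and 10 fell when adjusted over the list alone, with a median of -0.41 (adjusted p = 2.9e-17). The activation marker CD69 fell by 1.46 ± 0.27, RGS1 by 1.00 ± 0.21 and CD38 by 0.75 ± 0.11. Genes of cholesterol synthesis were lower as well: 9 of 24 fell and 0 rose, 12 when adjusted over the list alone, with a median of -0.15 (adjusted p = 1.1e-15). IDI1 (-0.44 ± 0.08), INSIG1 (-0.42 ± 0.07) and HMGCS1 (-0.32 ± 0.04), enzymes and a regulator of the pathway, were among them.

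Among the largest rises of UNC7263 were SAMD11 (0.90 ± 0.14), FPR1, a formyl peptide receptor (0.79 ± 0.22), RIN3 (0.77 ± 0.18), GNAO1 (0.77 ± 0.16) and ANGPT4 (0.76 ± 0.12). CCND1, cyclin D1, rose by 0.57 ± 0.07, LGR6 by 0.67 ± 0.08, DNAJC22 by 0.70 ± 0.09 and CBFA2T3, a transcriptional co-repressor, by 0.44 ± 0.05. TNFRSF14-AS1 (0.83 ± 0.24) is uncertain, since no source here says that counting used strand. CSRP2 (-0.89 ± 0.26) and ANK3 (-0.87 ± 0.20) were among the 10 largest falls. BCL6 fell by 0.23 ± 0.06. CBX8 (0.00 ± 0.09), RNF2 (-0.09 ± 0.08), EZH2 (-0.06 ± 0.04), PRDM1 (0.38 ± 0.23), CDKN1A (-0.25 ± 0.20), CDKN2A (0.01 ± 0.07) and MYC (0.02 ± 0.04) did not pass.

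Integrated stress response genes showed 0 of 28 members passing with UNC7263 in the authors' test, 2 lower at an unadjusted p under 0.05, and a median of -0.03 (adjusted p = 0.479). Interferon-stimulated genes were lower as a list, with a median of -0.29 (adjusted p = 1.9e-06), while 1 of 37 fell alone, SAMD9 (-0.32 ± 0.09), also when adjusted over the list alone. Ribosomal proteins had 6 of 35 lower and 1 higher, 10 and 1 when adjusted over the list alone (median -0.09, adjusted p = 2.4e-06). Germinal centre genes had 6 of 20 lower and 1 higher, 7 and 1 when adjusted over the list alone (adjusted p = 7.8e-06), including RGS13 (-0.39 ± 0.07) and MME (-0.39 ± 0.07). S phase (3 of 24 lower, adjusted p = 3.5e-05), B-cell markers (2 of 8 lower, adjusted p = 0.00018) and fatty acid synthesis (2 of 10 lower, adjusted p = 0.0021) were lower too, through PCNA (-0.24 ± 0.05), MS4A1 (-0.21 ± 0.06) and FASN (-0.19 ± 0.06) among others.

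Of PRC1 subunits 1 of 26 rose with UNC7263, BCOR (0.19 ± 0.05), and the list was not called (adjusted p = 0.950). G2/M genes were called higher, with 2 of 23 higher and 1 lower, and an adjusted p of 0.0017 that became an adjusted p of 0.118 at a correlation of 0.1. Lysosomal genes, 2 of 27 higher, had an adjusted p of 0.0043, or an adjusted p of 0.179 at that correlation. Ribosome biogenesis, 2 of 24 lower, also had an adjusted p of 0.0043, or an adjusted p of 0.161. Glycolysis, 1 of 16 lower, had an adjusted p of 0.031, or an adjusted p of 0.252. Epithelial markers were called higher (adjusted p = 0.046, and an adjusted p of 0.140 at 0.1) though 0 members had an adjusted p of their own and the 1 member with an estimate stood at -0.05. DCN fell by 0.46 ± 0.07 and TRAC by 0.50 ± 0.15, and the myeloid marker ITGAM rose by 0.30 ± 0.07. In all, 531 of 11047 genes changed, 144 upward and 387 downward, of which 0 and 1 exceeded 1 in the deposited log2 fold change. Of 36 lists tested 3 were higher and 10 lower, and 8 of these 13 were called at a correlation of 0.1. With log2 changes as the statistic immediate early genes, cholesterol synthesis and interferon-stimulated genes were called. By ranks epithelial markers were not called.

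The third question was how the compounds differ from each other in SUDHL4, where their doses are not given. Integrated stress response genes stood higher with UNC7040: 29 of 31 rose against UNC7263 and 0 fell, 30 when adjusted over the list alone, with a median of 1.10 (adjusted p = 9.9e-178). ATF5 differed by 2.82 ± 0.07, with a 95% interval from 2.68 to 2.96, and PSAT1 by 1.78 ± 0.06. CHAC1 differed by 4.74 ± 0.41, INHBE by 5.44 ± 0.41, ASS1 by 3.35 ± 0.12 and BCAT1, which starts the breakdown of branched-chain amino acids, by 1.32 ± 0.06. SPX (3.75 ± 0.21), ULBP1 (3.36 ± 0.39), MFAP4 (3.22 ± 0.29), CADPS (3.08 ± 0.41), SLC6A9 (2.61 ± 0.14) and STC2 (2.33 ± 0.10) complete the 10 largest.

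Cholesterol synthesis and immediate early genes were also higher with UNC7040 than with UNC7263. In the first list 18 of 24 were higher and 0 lower, 20 when adjusted over the list alone, with a median of 0.26 (adjusted p = 5.9e-13), such as INSIG1 (0.57 ± 0.07), MSMO1 (0.51 ± 0.06) and HMGCS1 (0.48 ± 0.04). In the second 10 of 22 were higher and 0 lower, also when adjusted over the list alone, with a median of 0.36 (adjusted p = 1.2e-06), such as ETV5 (1.41 ± 0.14) and FOS (0.84 ± 0.11). Both lists were lower with UNC7263 against DMSO, and of the 2 only cholesterol synthesis was called with UNC7040 against DMSO, as higher, a call lost at a correlation of 0.1 (adjusted p = 0.112). Fatty acid synthesis had 6 of 11 higher and 1 lower (median 0.31, adjusted p = 0.00063), with FADS1 at 0.47 ± 0.06 and SREBF1, its transcription factor, at 0.34 ± 0.07.

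Lower with UNC7040 than with UNC7263 were G2/M genes, with 16 of 24 lower and 0 higher, 18 when adjusted over the list alone, and a median of -0.23 (adjusted p = 1.9e-13). The mitotic genes PLK1 (-0.40 ± 0.05), KIF20A (-0.39 ± 0.05) and CDC20 (-0.38 ± 0.04) were among them. Respiratory chain genes had 10 of 20 lower, 14 when adjusted over the list alone (median -0.21, adjusted p = 1.9e-08). Ribosome biogenesis had 11 of 24 lower, 13 when adjusted over the list alone (median -0.15, adjusted p = 1.1e-05), and heat-shock genes 7 of 14, 8 when adjusted over the list alone (median -0.20, adjusted p = 9.2e-05). Interferon-stimulated genes had 8 of 40 lower, 12 when adjusted over the list alone, with a median of -0.32 and IFIT1 at -1.49 ± 0.36. Their adjusted p of 0.0001 became an adjusted p of 0.0708 at a correlation of 0.1. The largest falls were those of FER1L6 (-2.44 ± 0.41), TNNI1 (-1.75 ± 0.17), CDH19 (-1.73 ± 0.37), VNN1 (-1.70 ± 0.25), ATXN1 (-1.62 ± 0.32) and AGR2 (-1.60 ± 0.41), and CXCR3 fell by 1.55 ± 0.14.

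Ribosomal proteins were higher with UNC7040 than with UNC7263 in 15 of 35 cases, 16 when adjusted over the list alone (median 0.14, adjusted p = 9.6e-09). NF-kB targets had 6 of 16 higher (median 0.31, adjusted p = 2.0e-05), with LTA at 0.90 ± 0.11 and NFKB2 at 0.80 ± 0.05. NRF2 targets had 5 of 15 higher and MHC class I genes 6 of 12 higher and 1 lower (adjusted p = 9.8e-05 for each). By ranks the adjusted p of MHC class I genes by cameraPR was 0.0977. PRC1 subunits had 8 of 26 higher and 0 lower, 8 and 1 when adjusted over the list alone, with BMI1 at 0.79 ± 0.07 and BCORL1 at 0.42 ± 0.09. Germinal centre genes had 10 of 24 higher and 3 lower, with CD38 at 1.00 ± 0.11. For both of these lists the adjusted p was 0.0057, and it became an adjusted p of 0.0532 at a correlation of 0.05 and an adjusted p of 0.146 at 0.1. B-cell markers, 3 of 8 higher and 3 lower with CD22 at 0.90 ± 0.05, had an adjusted p of 0.0466, or an adjusted p of 0.0874 at 0.05; their median of -0.003 was of opposite sign to their test.

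CBX8 differed between the compounds by -0.03 ± 0.09, with a 95% interval from -0.21 to 0.15. CDKN1A (0.81 ± 0.20) and BCL6 (0.28 ± 0.06) were higher with UNC7040 and EZH2 lower (-0.14 ± 0.04), while RNF2 (0.16 ± 0.08), PRDM1 (-0.03 ± 0.23), CDKN2A (0.03 ± 0.07) and MYC (-0.00 ± 0.04) did not pass. Among markers of other cells, TRAC was higher (1.15 ± 0.14), and DCN (-0.81 ± 0.07), PDGFRB (-0.93 ± 0.25) and ITGAM (-0.43 ± 0.07) were lower. In all, 2330 of 15466 genes differed by the Wald test, 1197 upward and 1133 downward, 108 and 93 of them by more than 1 in the unshrunken difference, a scale unlike the deposited one used for the counts above. Of 33 lists tested 11 were higher and 5 lower, 12 of these 16 were called at a correlation of 0.1, and with log2 changes as the statistic ribosomal proteins, heat shock, MHC class I, fatty acid synthesis, PRC1, germinal centre and B-cell markers were not called. By ranks MHC class I, germinal centre and B-cell markers were not called. With the DMSO variance left in, the count of differing genes fell to 834.

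**Figure D2:**
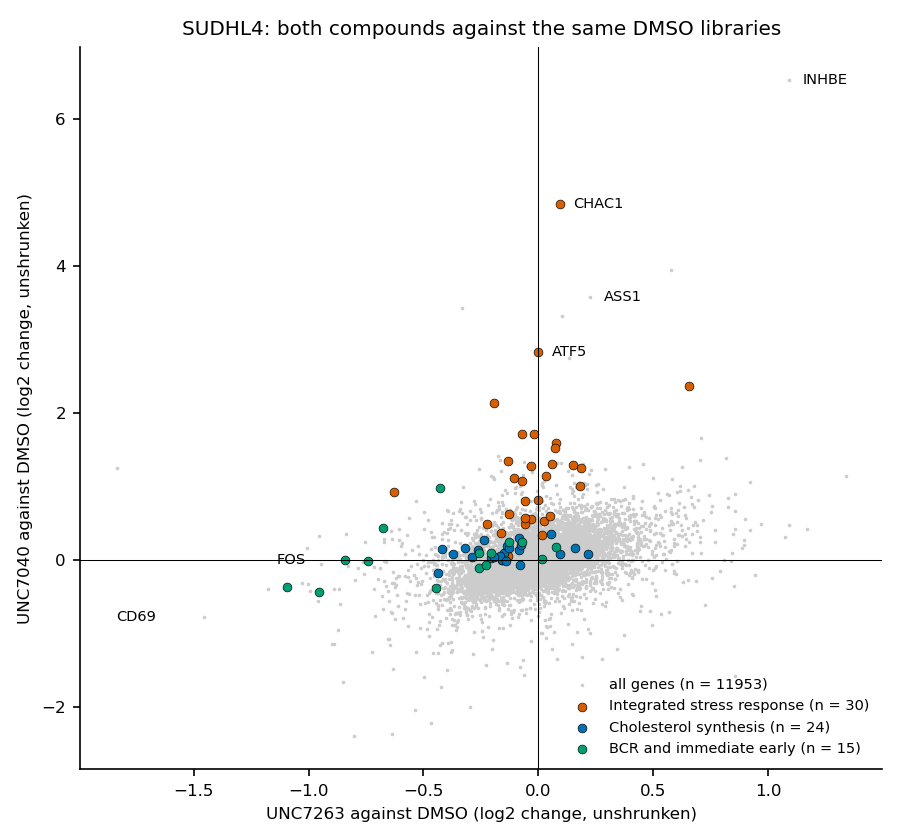
Unshrunken log2 changes against DMSO in SUDHL4 for UNC7263 (horizontal) and UNC7040 (vertical), 1 point per gene, 11953 genes with a mean of at least 50, 3 libraries per group. Integrated stress response genes (orange) spread upward from UNC7263 values near 0, and cholesterol (blue) and immediate early genes (green) lie mostly left of 0.

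Genes that changed with both compounds against DMSO were compared next. Of the 11047 genes tested for both, 79 rose with both, where independent lists of that length would share 19.4, and 273 fell with both, against 64.9. Of the genes called with UNC7263, 14 that rose fell with UNC7040 and 16 that fell rose. Across 11953 genes, which are not independent replicates, the changes had Pearson's r of 0.412 and Spearman's rho of 0.459, beside a mean r of 0.499 in 100 simulated draws of unchanged groups. Their covariance was 0.0218 against 0.0107 in the simulation, a difference of 0.0111. With genes of a mean of at least 10 it was 0.0653 against 0.0568, with a simulated maximum of 0.0636, a ratio of 1.15 in place of 2.03. At a mean of at least 200 it was 0.0147 against 0.00464, a ratio of 3.18. The 3 DMSO libraries could not be split, so part of the excess in shared calls may come from the shared controls. The standard deviation of the changes was 0.298 for UNC7040 and 0.177 for UNC7263, a ratio of 1.68, and 2.59 after removal of the measurement error.

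**Figure D3:**
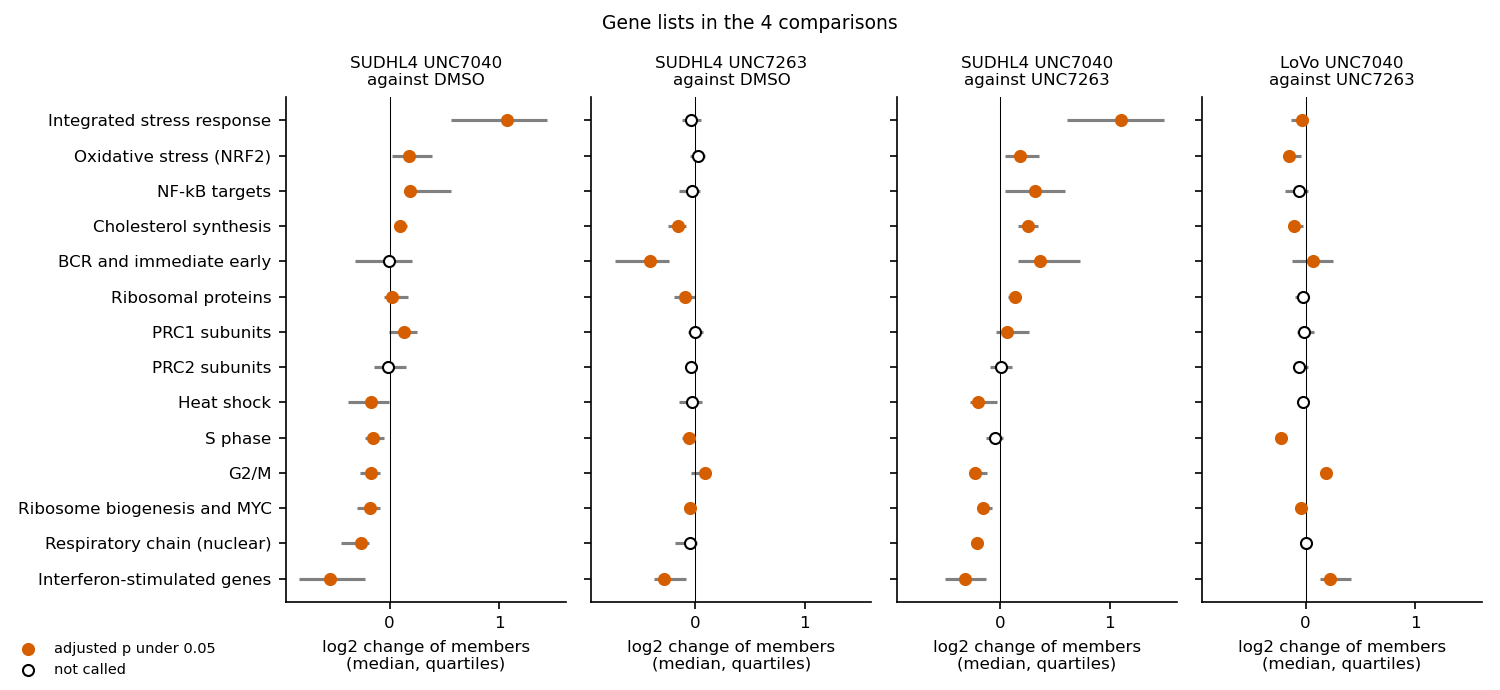
Medians (points) and quartiles (lines) of the unshrunken log2 changes of the members of 14 gene lists in the 4 comparisons; filled points have an adjusted p under 0.05 by cameraPR at a correlation of 0.01. Integrated stress response genes stand at 1.07 and 1.10 in the UNC7040 comparisons of SUDHL4, and interferon-stimulated genes at -0.32 in SUDHL4 against 0.23 in LoVo for UNC7040 against UNC7263.

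The fourth question was how the compounds differ in LoVo, for which the series holds no DMSO libraries for RNA. Rises and falls in LoVo are therefore those of UNC7040 against UNC7263, and which compound moved a gene cannot be told. Differentiation genes of the intestine were higher with UNC7040 than with UNC7263: KRT20, a keratin of mature enterocytes, by 1.31 ± 0.19, and CDH17, an intestinal cadherin, by 0.28 ± 0.05. Of 12 listed members 2 rose, 6 when adjusted over the list alone, with a median of 0.20 (adjusted p = 3.3e-08). LGR5, the receptor that marks intestinal stem cells, fell by 0.49 ± 0.06, and PTGS2, cyclooxygenase 2, fell by 1.21 ± 0.12. LGR5 was the 1 of 13 Wnt and stem genes that passed, 2 fell when adjusted over the list alone, and the list's adjusted p of 0.015 became an adjusted p of 0.0633 at a correlation of 0.05.

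Interferon-stimulated genes were higher with UNC7040 in LoVo, with 5 of 35 higher and 0 lower, 14 when adjusted over the list alone, and a median of 0.23 (adjusted p = 2.0e-20). IFI27 (0.92 ± 0.21) and SAMD9 (0.65 ± 0.16) were among them. MHC class I genes had 0 of 12 passing in the authors' test, 4 higher at an unadjusted p under 0.05 and 4 when adjusted over the list alone, with a median of 0.15 (adjusted p = 1.2e-06). Cell-cycle groups moved apart: G2/M genes had 3 of 23 higher, 12 when adjusted over the list alone, with a median of 0.18 (adjusted p = 3.6e-18), and S-phase genes 1 of 23 lower, 12 when adjusted over the list alone, with a median of -0.23 (adjusted p = 1.2e-19). MKI67 (0.31 ± 0.07) and CENPE (0.46 ± 0.11) rose and the helicase subunit MCM7 fell by 0.23 ± 0.06.

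Unfolded protein response genes were lower in LoVo, with 1 of 16 lower, 5 when adjusted over the list alone, and a median of -0.15 (adjusted p = 1.6e-11); the 1 was HSPA5, the main chaperone of the endoplasmic reticulum (-0.20 ± 0.05). NRF2 targets had 2 of 16 lower, 4 when adjusted over the list alone (median -0.15, adjusted p = 3.3e-08), TXNRD1 (-0.26 ± 0.05) and AKR1C1 (-0.52 ± 0.14). Fatty acid synthesis had 2 of 12 lower, 3 when adjusted over the list alone (median -0.14, adjusted p = 1.5e-06), FASN (-0.22 ± 0.05) and ME1 (-0.28 ± 0.06). Immediate early genes had 3 of 19 higher and 1 lower, 5 and 2 when adjusted over the list alone, with FOS at 0.74 ± 0.11, EGR1 at 0.60 ± 0.07, JUN at 0.41 ± 0.08 and IER3 at -0.34 ± 0.08; their adjusted p of 0.0055 became an adjusted p of 0.0531 at a correlation of 0.05. Epithelial markers had 1 of 8 higher, KRT19 (0.41 ± 0.06), and 3 when adjusted over the list alone (median 0.11, adjusted p = 3.7e-07).

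Integrated stress response genes showed 0 of 31 passing in LoVo in the authors' test, and 1 higher and 7 lower at an unadjusted p under 0.05. Their median was -0.03, and an adjusted p of 0.005 became an adjusted p of 0.0598 at a correlation of 0.05. Cholesterol synthesis likewise had 0 of 25 passing, 3 lower at an unadjusted p under 0.05, and an adjusted p of 0.0023 that became an adjusted p of 0.128 at 0.1. PRC1 subunits had 0 of 26 passing and 1 lower at an unadjusted p under 0.05 (adjusted p = 0.551). Neither PRC2 subunits (0 of 13, 0 unadjusted) nor HOX genes (0 of 21, 1 lower unadjusted) were called. Of 23 developmental regulators with an adjusted p, from 60 listed, 1 rose, TBX3 (0.32 ± 0.08). CBX8 (0.10 ± 0.14), RNF2 (-0.12 ± 0.11), EZH2 (-0.12 ± 0.09), PRDM1 (0.09 ± 0.16), BCL6 (-0.02 ± 0.18), CDKN1A (0.08 ± 0.07), CDKN2A (0.60 ± 0.35) and MYC (-0.12 ± 0.06) did not pass.

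Among the largest falls in LoVo were IGFBP3 (-1.33 ± 0.24) and IGFBP1 (-0.91 ± 0.16), which bind insulin-like growth factors, TM4SF1 (-0.84 ± 0.13), IGFL2 (-0.84 ± 0.17), SOD3 (-0.75 ± 0.15), GLIS3 (-0.74 ± 0.18) and the aquaporin AQP3 (-0.65 ± 0.12). FCGBP, a mucus protein, rose by 0.86 ± 0.21, PRLR by 0.76 ± 0.18, COL17A1 by 0.60 ± 0.09 and LGALS3 by 0.40 ± 0.05. PPIAP22 (0.67 ± 0.11) is a pseudogene close in sequence to its parent gene and is uncertain. Further lists were called at the preset of 0.01 and not at 0.1: ribosome biogenesis (lower, adjusted p = 0.175 at 0.1), histones (higher, adjusted p = 0.153), metallothioneins (lower, adjusted p = 0.128), plasma cell genes (lower, adjusted p = 0.143) and p53 targets (higher, adjusted p = 0.261). In all, 113 of 11727 genes changed in LoVo, 56 upward and 57 downward, of which 1 and 2 exceeded 1 in the deposited log2 fold change, and 851 had an unadjusted p under 0.05. Of 34 lists tested 8 were higher and 10 lower, and 9 of these 18 were called at a correlation of 0.1. With log2 changes as the statistic epithelial markers, fatty acid and cholesterol synthesis, integrated stress response, ribosome biogenesis, Wnt, plasma cell and p53 lists were not called. By ranks immediate early genes, metallothioneins and the Wnt and plasma cell lists were not called.

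UNC7040 against UNC7263 is the contrast that both cell lines share. The test per gene was planned, and the list tests between the lines were chosen only after the results were seen. Stress response, G2/M and interferon-stimulated genes differed between the lines: the stress list stood 1.13 higher in SUDHL4 by the median member (adjusted p = 3.5e-202), the G2/M list at -0.43 (adjusted p = 1.5e-24) and the interferon list at -0.56 (adjusted p = 6.9e-15). FOS, EGR1 and ALDH2 were higher with UNC7040 than with UNC7263 in both lines, and HSPA5, MCM7 and SNHG12 were lower in both. Among 9819 genes tested in both, these 3 and 3 compare with 2.94 and 2.71 for independent lists (one-sided exact hypergeometric p = 0.575 and 0.516). LIMA1, ID2, OAS1, SAMD9, FAM102A, CENPE and HMMR were lower in SUDHL4 and higher in LoVo, and LCK, GAS5, CCNB1IP1 and PABPC1 did the opposite. These 7 and 4 genes compare with 2.80 and 2.84 for independent lists, an excess that was not tested. LIMA1 stood at -0.83 ± 0.12 in SUDHL4 and 0.39 ± 0.06 in LoVo. Across 10279 genes, which are not independent replicates, Pearson's r was -0.032 and Spearman's rho -0.019. The change differed between the lines in 690 genes, and as a signed value it was higher in SUDHL4 for 426 and lower for 264. A higher signed change need not be a stronger response. Whether doses and times were the same in both lines is not given in the sources used here.

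**Figure D4:**
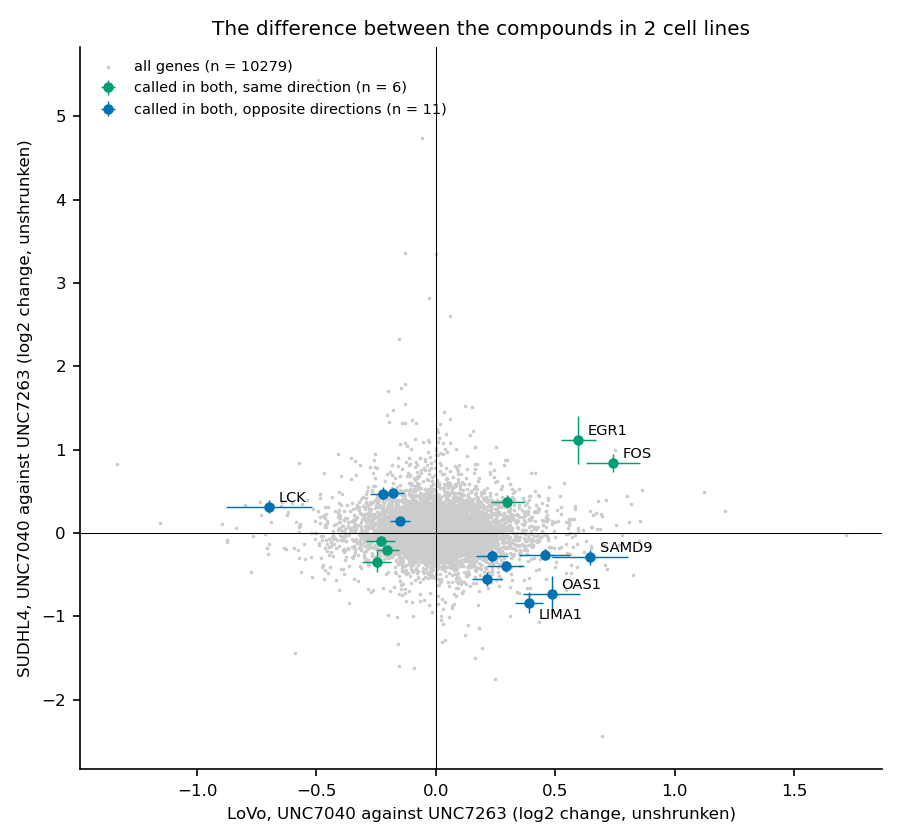
Unshrunken log2 difference of UNC7040 against UNC7263 in LoVo (horizontal, 2 libraries per group) and SUDHL4 (vertical, 3 per group), 1 point per gene, 10279 genes with a mean of at least 50 in both. Bars are 1 standard error for the genes called in both lines, 6 with the same direction and 11 with opposite directions; r across all genes is -0.032.

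Calls were also split by quartile of mean expression. With UNC7040 in SUDHL4, 4.63% of the tested genes in the lowest quartile rose and 3.31% fell, and in the highest quartile 14.9% rose and 30.7% fell. Without a limit on size, called rises were therefore less frequent per tested gene in the lowest quartile, and so were called falls. Rises made up 58.3% of the calls in the lowest quartile against 32.7% in the highest (odds ratio 2.88, two-sided Fisher's exact p = 6.0e-15). These shares differed because falls were more frequent still in the highest quartile. The quartiles hold only genes with an adjusted p. A call also depends on the precision of the estimate, which was not compared between quartiles. The call rates therefore do not show that weakly expressed genes responded less. Among calls above 1 on the log2 scale the order of the shares was reversed, 47.0% against 100%, which are the 7 calls left in the highest quartile, 7 rises and 0 falls (p = 0.0119 by the same exact test). With that limit rises per gene were more frequent in the lowest quartile, 0.933% against 0.211%. With UNC7263, 0.797% rose and 0.941% fell in the lowest quartile, and 2.17% rose and 7.57% fell in the highest, so that rises made up 45.8% and 22.3% of the calls (odds ratio 2.95, exact p = 0.0011). In LoVo rises made up 57.1% and 49.3% of the calls (odds ratio 1.37, exact p = 1). With quartiles of the derived control-group mean, UNC7263 in LoVo, the odds ratios were larger: 4.57 for UNC7040, 5.29 for UNC7263 and 4.88 in LoVo (exact p = 0.184 for LoVo). That mean is derived from the same change that defines a rise or a fall, which moves rises to lower quartiles. The larger odds ratios are therefore not separate evidence. In LoVo the lowest of these quartiles held only 4 rises and 1 fall.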

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

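Differences between the cell lines in the response to UNC7040 against UNC7263 are given first. The test per gene was planned, while the list tests between the lines and all tests of technical explanations in this part were chosen only after the results were seen. By the z test of the difference, 690 genes responded differently in SUDHL4 and LoVo. Values below are the log2 change in SUDHL4 minus that in LoVo.

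Stress response genes had a median difference of 1.13. The 5 largest test statistics upward were those of ATF5 (2.86), ASS1 (3.35), STC2 (2.48), PSAT1 (1.91) and BCAT1 (1.45). The 5 largest downward were those of LIMA1 (-1.23), MTATP8P1 (-1.31), ID2 (-0.77), RASSF6 (-1.33) and MYO5B (-0.70), and MTATP8P1 is a copy of a mitochondrial gene and uncertain. Besides LIMA1 and ID2, genes called in both lines with opposite signs were FAM102A (-0.69), CENPE (-0.72), HMMR (-0.51), SAMD9 (-0.94) and OAS1 (-1.22), and in the other direction PABPC1 (0.30), LCK (1.02), CCNB1IP1 (0.69) and GAS5 (0.66).

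By list medians the difference was -0.43 for G2/M genes, -0.56 for interferon-stimulated genes and -0.23 for the respiratory chain. It was 0.37 for cholesterol synthesis, 0.17 for ribosomal proteins, 0.34 for NRF2 targets, 0.32 for fatty acid synthesis and 0.30 for plasma cell genes. Lists whose difference was called at the preset correlation of 0.01 and not at 0.1 were S phase (0.18, adjusted p = 0.0527 at 0.1), B-cell receptor and immediate early genes (0.24, adjusted p = 0.0527), heat shock (-0.13, adjusted p = 0.0527) and NF-kB targets (0.17, adjusted p = 0.0527). The same holds for glycolysis and hypoxia (0.17, adjusted p = 0.107), the unfolded protein response (0.0577, adjusted p = 0.117), PRC1 subunits (0.0891, adjusted p = 0.188) and ribosome biogenesis (-0.12, adjusted p = 0.178). Doses and times are not given for either line, so these differences cannot be assigned to the lines themselves.

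The rise of integrated stress response genes with UNC7040 in SUDHL4 was weighed first. A trend with expression level left by the normalization would also move other lists of like abundance, but the highest median of 10000 random lists matched on mean count was 0.132, against 1.07 for the stress list. DMSO libraries low for these genes would raise them with UNC7263 too, where their median was -0.03. The labels give no batch, day or date, so a difference between batches could not be examined. No biological explanation was tested, and a response to the compound remains a hypothesis.

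Copies of mitochondrial genes in the nuclear genome were weighed second: of 13 abundant copies, with 3.26% of all normalized counts, 8 fell with UNC7040 and 2 rose, MTND1P23 (0.47 ± 0.06) and MTND2P28 (0.23 ± 0.06), while with UNC7263 against the same DMSO libraries 5 rose and 0 fell, these 2 (0.32 and 0.26) and MTATP6P1 (0.20) and MTND6P4 (0.19), which fell with UNC7040, among them. A lower share of mitochondrial RNA, even across genes, would as the whole cause move all copies alike. Against UNC7263 12 of 13 lay below 0, but the highest, MTND1P23, and the lowest, MTCO3P12, were 1.15 ± 0.08 apart. An even fall therefore stays open only as a part. A fall of mitochondrial RNA that differs between genes was not tested and stays open. Transcription of the chromosome 1 copies as one unit would also move them alike if their RNAs were equally stable, which is unknown. These same 2 copies lie there, with a gap of 1.45 ± 0.08 against DMSO. Reads of the mitochondrial genome counted on its nuclear copies stay open, since 0 mitochondrial genes are among the genes measured. No biological explanation was tested.

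Lower interferon-stimulated genes with UNC7040 in SUDHL4 were weighed last. DMSO libraries high for these genes as the whole cause would leave no difference from UNC7263, but the median of UNC7040 against UNC7263 was -0.32, with 8 of 40 members lower, and that call has an adjusted p of 0.0708 at a correlation of 0.1. With UNC7263 against the same DMSO libraries the median was -0.29, so DMSO libraries high for these genes may account for part of the fall. Spread between libraries of one group in these genes stays open as well, since their median dispersion was 4.88 times that of matched lists. No biological explanation was tested.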

How the results depend on the processing

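No paired analysis was possible because the tables hold no per-sample values, and for the same reason leaving out replicates, other normalizations or tools and other splits of the samples were not run. The 3 alternatives with shrunken estimates were chosen only after the results were seen. For the difference between the compounds the plan had named the deposited, shrunken changes with the DMSO variance removed, a setting that was not run. Of 3091 alternative values 2669 kept their side of the threshold or stayed close, 401 were weaker, 20 moved and 1 reversed. Among 2740 values of named genes 322 were weaker and 0 reversed. Most named genes were chosen because they were called, and most alternatives reuse the same estimates. Their values could therefore do little but stay or weaken, so these counts do not measure robustness. A log2 limit of 1 left 113 genes for UNC7040, 1 for UNC7263 and 3 in LoVo, fewer because the limit removes small changes. A threshold of 0.01 gave 218 genes for UNC7263, 73 in LoVo and 1523 between the compounds in SUDHL4, and a threshold of 0.1 gave 863 for UNC7263. Between the compounds, 834 genes passed with the DMSO variance left in, which widens every error. With shrunken estimates 1009 passed, and there the DMSO variance was left in as well. That count therefore compares with 834 and not with the 2330 of the main test. At a correlation of 0.1 list calls came to 8 for UNC7263 and 9 in LoVo, and in LoVo to 10 at 0.05. With log2 changes as the statistic they came to 8 for UNC7040, 3 for UNC7263, 9 between the compounds and 10 in LoVo; the cause was not tested. The correlation of both compounds was 0.436 at a mean of at least 10, 0.433 at 200 and 0.317 with shrunken estimates, against 0.412. Between cell lines r was -0.0056 at a mean of at least 10, against -0.032. The share of rises by expression quartile for UNC7040 reversed among changes over 1 (exact p = 0.0119), the cause was not tested, and for UNC7263 and LoVo that limit left too few calls for a value. Re-centring moved the share of rises by at most 4.42 points. Depth per library is unknown, so what it limits was not tested.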

Other observations

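All 5 lists of this part, and their tests, were chosen only after the results were seen, with adjustment over these 5 lists. Mitochondrial ribosomal proteins, which build the ribosome inside mitochondria, were lower with UNC7040 against DMSO in SUDHL4: 45 of 75 fell and 1 rose, with a median of -0.26 (adjusted p = 4.1e-18). MRPL15 (-0.56 ± 0.08), MRPL13 (-0.53 ± 0.08) and MRPS31 (-0.51 ± 0.08) were among them. With UNC7263 10 of 74 fell, with a median of -0.09 (adjusted p = 3.9e-09), and UNC7040 stood below UNC7263 in 13 of 76 (median -0.15, adjusted p = 1.2e-06). In LoVo 0 of 73 passed in the authors' test, 0 reached an unadjusted p under 0.05, and the list was not called (adjusted p = 0.701). Mitochondrial aminoacyl-tRNA synthetases, which charge tRNAs there, had 7 of 16 lower and 1 higher with UNC7040 (median -0.18, adjusted p = 0.0013), such as CARS2 (-0.35 ± 0.06).

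Amino acid transporters were higher with UNC7040 against DMSO: 7 of 9 rose and 1 fell, with a median of 0.59 (adjusted p = 6.7e-32). SLC1A4 (0.88 ± 0.07), SLC7A1 (0.68 ± 0.05) and SLC1A5 (0.59 ± 0.05) rose, and SLC38A5 fell by 0.20 ± 0.06. In LoVo, with UNC7040 against UNC7263, the list was lower (median -0.11, adjusted p = 0.0003), while 0 of 9 passed in the authors' test and 3 were lower at an unadjusted p under 0.05. Cytosolic aminoacyl-tRNA synthetases moved both ways, with 7 of 17 higher and 6 lower; their median was 0.08 and their test pointed up (adjusted p = 1.1e-09). CARS1 (0.98 ± 0.06) and MARS1 (0.78 ± 0.05) rose, and RARS1 (-0.40 ± 0.07) and FARSB (-0.25 ± 0.05) fell. Host genes of small nucleolar RNAs had 5 of 21 higher and 5 lower with UNC7040, and the list was not called (adjusted p = 0.395); its median was -0.05 while its test pointed up. With UNC7263 against DMSO 2 of 20 fell, with a median of -0.08, and an adjusted p of 0.00083 became an adjusted p of 0.058 at a correlation of 0.1. With UNC7040 against UNC7263 in SUDHL4 the test pointed up, with 5 of 21 higher and 3 lower and a median of 0.06, and an adjusted p of 0.0074 became an adjusted p of 0.09 at that correlation. In LoVo 2 of 18 host genes were lower with UNC7040 against UNC7263, GAS5 (-0.18 ± 0.05) and SNHG12 (-0.25 ± 0.06), with a median of -0.14 (adjusted p = 5.7e-11).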
